A study of Bos taurus with 14 samples.

How the data were processed

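Mammary gland tissue of 14 Holstein-Friesian cows was profiled on Affymetrix bovine arrays, with 1 array per cow. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was made from it by the manufacturer's standard procedure. Per the stated design, the cows were paired in 7 blocks by parity, expected calving date and earlier milk yield. By the labels, parity differed within 4 of the 7 pairs, and expected calving differed by up to 48 days within a pair. Within each block 1 cow was allocated at random to the Omega diet, which included linseed, and 1 to the Control diet. The day on which tissue was taken is not given in the sources used here.

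The deposited values are log2 intensities in a single table of 10852 rows. RMA and GCRMA, which are methods of background correction, normalization and summary for Affymetrix arrays, are named in the submitters' processing notes, without versions. Which of them made the deposited log2 values is not given in the sources used here. The values ran from 2.26 to 14.8, and the medians of the 14 arrays lay between 5.70 and 5.76. Such values are compressed at both ends of the scale, so differences of dim and of very bright transcripts can be understated. The most abundant milk protein transcripts lay close to the upper end of the scale.

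Of the rows, 112 were control probe sets of the array maker and 10740 were probe sets named by RefSeq accession. The accessions were matched without versions to the RefSeq gene table of assembly ARS-UCD2.0. This gave 1 symbol to each of 6749 probe sets, for 6697 symbols, and left 3991 unnamed. All 3428 predicted messenger accessions and all 348 predicted non-coding accessions stayed unnamed. FASN, FADS1 and CSN2 had no probe set named in this way and are not analysed here. Unnamed probe sets stayed in the tests.

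Probe sets were tested where their mean over the 14 arrays exceeded the 30th percentile, a log2 value of 4.59. This left 7518 probe sets, of which 4969 had a symbol, for 4932 symbols. Among the tested probe sets, 485 had values equal to those of another probe set on every array, so that 7250 distinct sets of values were tested. Where a symbol had several probe sets, the one with the highest mean was used. No table column was left without a cow.

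Differences were fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The diet fit had the block as a fixed effect. Parity was compared between the 4 cows with a parity label of 1 and the 10 cows with a higher label, with diet as a fixed effect and the block as a random effect (duplicateCorrelation). A further fit tested whether the diet difference varied with parity class. The pairing came from the block labels and the stated design. Deviations from the diet means correlated within blocks at r from -0.47 to 0.32 across probe sets, and above 0.1 in 3 of the 7 blocks. The limma test of the diet was set beside an exact two-sided sign-flip test over the 7 blocks, whose smallest possible p is 0.0156.

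Before the data were examined, 37 gene lists for mammary metabolism, immune response and cell types were fixed, with 917 entries, of which 637 matched a symbol. The 34 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. The list test for parity had diet and no block, and the list test for the interaction was added after seeing the data. A list score of a cow is the mean over members of log2 values centred on each gene's mean over the 14 cows.

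The genes named were also fixed by a rule. For diet and parity, the 10 largest rises and the 10 largest falls past the threshold were to be named, filled up by the smallest unadjusted p where too few passed. None passed, so every gene named under this rule was chosen by its unadjusted p. For each described list, up to 4 members with the smallest unadjusted p were named, and for the interaction the 3 genes with the smallest p. Some list members that this rule selects are not reported here. A fixed set of lipid and milk protein genes was given in every case. Genes named for the 2 Control cows that stood apart were chosen after their values were seen.

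The fits were tested on simulated data with 50 changed probe sets at each size among 7518. The diet fit recovered 58% of them at a log2 change of 0.5, 94% at 1, 92% at 1.5 and 100% at 2. The parity fit recovered 48%, 84%, 94% and 100% at the same sizes, and the interaction fit recovered 0%, 38%, 62% and 80%. The simulated noise was independent between genes, which the real arrays are not. In the simulated diet data with 16 members of a list changed, camera called that list and 0 of 33 others.

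Alternatives covered the block, the filter, the variance model, array weights, the normalization, covariates and each block left out in turn. For lists, the set test and the choice of probe set were also varied. Leaving out the blocks or cows whose arrays stood apart, the hybridization controls as a covariate and counting equal rows a single time were added after seeing the data. The number of cows limits the precision of every value.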

Results

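The mammary gland of lactating dairy cows makes milk fat, protein and lactose, and linseed supplies alpha-linolenic acid, an omega-3 fatty acid. Gene expression was measured in mammary tissue of 14 Holstein-Friesian cows in 7 blocks. In each block 1 cow received a concentrate with linseed (Omega, n = 7) and 1 received a concentrate without it (Control, n = 7), from 3 weeks before expected calving to 6 weeks after it. The labels gave parity 1 for 4 cows, parity 2 for 2 cows and parity 3 or higher for 8 cows. The design text counts parities differently, with no first-parity cows, so the labels were used as given. The 4 cows labelled parity 1 had recorded milk of a previous lactation, between 2110 and 2771, so the label does not mean a first lactation at sampling. Array medians lay between 5.70 and 5.76 log2.

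The diet groups had similar means in the recorded traits other than parity. Milk over the first 100 days of the previous lactation was 3767 ± 1012 in Omega and 3796 ± 933 in Control cows (SD, n = 7 each, unit not given in the labels), with exact sign-flip p = 0.594. Parity was 2.71 ± 1.38 in Omega and 3.29 ± 2.14 in Control cows (SD, n = 7 each), lower in Omega in 3 blocks and higher in 1. It had the smallest exact p of the 6 traits compared, at 0.375, and all 6 had a Benjamini-Hochberg value of 0.938. These tests compare 7 pairs and cannot exclude an imbalance.

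The arrays of the Control cows of blocks 302 and 304 lay apart from the other 12. On the first principal component, which held 51.0% of the variance, they stood at 43.7 and 46.4, and the other 12 cows lay from -18.1 to 10.8. Their median correlations with the remaining arrays were 0.926 and 0.912, against 0.962 to 0.980 in the others. The 2 arrays correlated with each other at 0.977. SAA3, an acute-phase protein of the udder, reached 12.80 and 13.82 log2 in these cows and 6.70 to 10.20 in the others. LPL, the lipase that releases fatty acids from blood lipoproteins, was at 11.07 and 11.10 log2, below the range of 11.49 to 13.30. Both cows belong to the Control group, so each diet difference given here includes them.

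**Figure D1:**
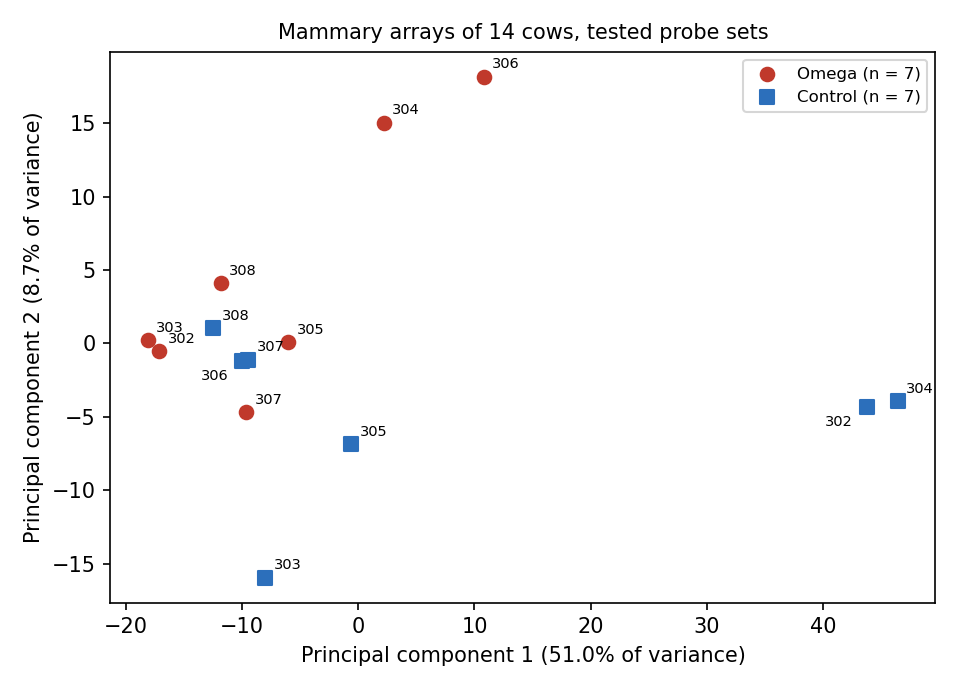
Scores of the 14 arrays on principal components 1 and 2 of the tested probe sets (axes in log2 units, with the percent of variance), Omega cows as circles and Control cows as squares, numbered by block. The Control cows of blocks 302 and 304 sit at 43.7 and 46.4 on component 1, and the highest of the other 12 sits at 10.8.

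The diet comparison asked how linseed in the transition period altered expression in the gland. No single gene passed the test. With a preset correlation, cholesterol synthesis and milk fat globule genes were higher as groups in Omega cows, and ribosomal protein and connective tissue transcripts were lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.841). The group differences were smaller than 1.3-fold. Without the 2 blocks whose Control cows stood apart, 3 calls were lost and the ribosomal median went from -0.23 to -0.08 log2. The same 3 calls were lost with array weights, which kept all cows but can give deviating arrays less weight.

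With limma, 0 of 7518 probe sets had an adjusted p under 0.05, and the smallest adjusted p was 0.447. At an unadjusted p under 0.05 there were 827 probe sets, 284 higher and 543 lower, where 375.9 would be expected by chance. Centring each array on its median turned this split to 436 higher and 351 lower, and quantile normalization to 393 and 388. The exact sign-flip test also gave 0 probe sets after adjustment and 768 at an unadjusted p under 0.05. In 268 probe sets all 7 blocks had the same sign, against 117.5 expected. The median 95% confidence interval reached 0.26 log2 to either side, or 1.19-fold, and 17 probe sets differed by over 1 log2. Leaving out block 303 or 304 brought the 827 probe sets to 516 or 434.

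Among the genes with the smallest p, DYRK3, a protein kinase, was 0.55 log2 higher in Omega cows (95% confidence interval 0.32 to 0.78), at 7.11 ± 0.13 against 6.56 ± 0.30 (SD, n = 7 each). SLC5A1, a sodium-coupled glucose transporter, was 0.57 higher (0.32 to 0.81), or 1.48-fold, and higher in 7 of 7 blocks. ANKRD22 was 0.57 higher, SOX4, a transcription factor, 0.57 higher, and MOSPD1 0.59 higher. COQ2, an enzyme of ubiquinone synthesis, was 0.40 higher. AZGP1, a secreted glycoprotein linked to lipid mobilization, was 0.49 higher, in 6 of 7 blocks. RANGRF was 0.34 higher, NPFF, a neuropeptide precursor, 0.34 higher, and NCAPH, a condensin subunit, 0.31 higher. All 10 had an adjusted p of 0.447.

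On the lower side, TFPI2, an inhibitor of serine proteases, differed by -0.69 log2 (-0.99 to -0.40), with 8.65 ± 0.22 in Omega and 9.35 ± 0.42 in Control cows (SD, n = 7 each). WDR75, which takes part in ribosomal RNA production, differed by -0.63 and TMEM50B by -0.57. KLHL2, an adaptor of ubiquitin ligases, differed by -0.53, ITGB5, an integrin subunit, by -0.48, and AP4S1, an adaptor complex subunit, by -0.44. SRSF7, a splicing factor, differed by -0.43, C1QTNF7 by -0.42, RNF7 by -0.39 and TYW3, an enzyme of transfer RNA modification, by -0.39. These 10 were lower in 7 of 7 blocks and had an adjusted p of 0.447 in limma. For ITGB5, 1 Omega cow of block 304 lay far above the other Omega cows.

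**Figure D2:**
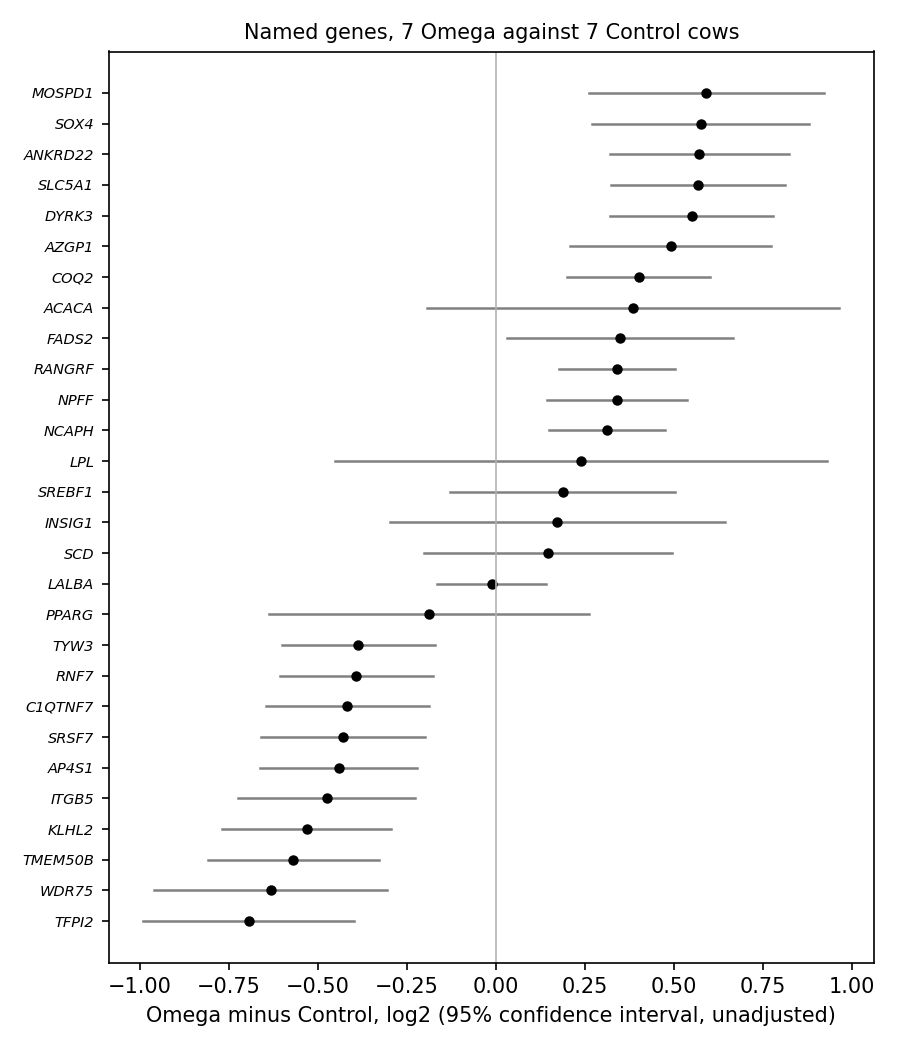
Difference between Omega and Control cows in log2 (x axis) for the 20 genes with the smallest p, 10 in each direction, and 8 lipid and milk protein genes named for any value (y axis), points with unadjusted 95% confidence intervals from limma with the block, n = 7 cows per diet. Among these, TFPI2 at -0.69 and MOSPD1 at 0.59 are the ends of the range, and none passed the adjusted threshold.

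Cholesterol synthesis and uptake genes were higher as a group in Omega cows, with 14 of 15 members higher and a median of 0.22 log2 (camera adjusted p = 0.00206). The call was lost with an estimated correlation (adjusted p = 0.841). FDFT1, which makes squalene, was 0.47 higher (0.10 to 0.83), PMVK, a kinase of the mevalonate pathway, 0.41, TM7SF2, a sterol reductase, 0.33, and MSMO1, a sterol oxidase, 0.26, each in 6 of 7 blocks, while the list score was higher in 4 of 7 (exact sign-flip p = 0.234). No member passed limma when adjusted over the list alone or over all probe sets. The list scores of the Control cows of blocks 302 and 304 were -0.29 and -0.71, against -0.07 to 0.30 in the other 12. Without these blocks the median was -0.01 log2 (adjusted p = 0.725), and without block 302 or 304 alone the adjusted p was 0.0552 or 0.0512.

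Genes of triacylglycerol synthesis and the milk fat globule were also higher as a group, with 12 of 16 members higher and a median of 0.23 log2 (camera adjusted p = 0.0121). With an estimated correlation the adjusted p was 0.841. CIDEA, a lipid droplet protein, was 0.79 higher (0.03 to 1.54), MUC15, a mucin of the globule membrane, 0.51, GPD1, which makes glycerol 3-phosphate, 0.43, and BSCL2, a protein of lipid droplet formation, 0.37. None of the 16 passed when adjusted over the list alone, and the list score was higher in 5 of 7 blocks (exact sign-flip p = 0.3125). The scores of the same 2 Control cows were -0.58 and -0.84, against -0.13 to 0.30. Without their blocks the median was -0.01 log2 (adjusted p = 0.725), and the call was also lost without block 302 alone (adjusted p = 0.314) or block 304 alone (0.181).

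Ribosomal protein transcripts were lower as a group in Omega cows, with 0 of 29 members higher and a median of -0.23 log2 (camera adjusted p = 4.48e-08). With an estimated correlation the adjusted p was 0.841. RPL7A differed by -0.34 (-0.62 to -0.06), RPL18 by -0.31 and RPL13 by -0.27, and 0 members passed when adjusted over the list alone. The list score was lower in 6 of 7 blocks, with exact sign-flip p = 0.0781. The 2 Control cows scored 0.31 and 0.41, above the range of -0.34 to 0.17. Without their blocks the median was -0.08 (adjusted p = 0.0128), and under quantile normalization it was -0.05 and the call was lost (adjusted p = 0.147).

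Fibroblast and connective tissue transcripts were lower as a group, with 1 of 16 members higher and a median of -0.30 log2 (camera adjusted p = 0.0124). With an estimated correlation the adjusted p was 0.841. DCN, a matrix proteoglycan, differed by -0.50 (-0.93 to -0.07), COL1A2, a collagen chain, by -0.45, VIM, an intermediate filament, by -0.40 and SPARC, a matrix glycoprotein, by -0.31. No member passed when adjusted over the list alone, and the list score was lower in 5 of 7 blocks (exact sign-flip p = 0.109). The 2 Control cows scored 0.68 and 0.58, against -0.30 to 0.27. Without their blocks the median was -0.11 (adjusted p = 0.141), and without block 302 alone the adjusted p was 0.168.

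**Figure D3:**
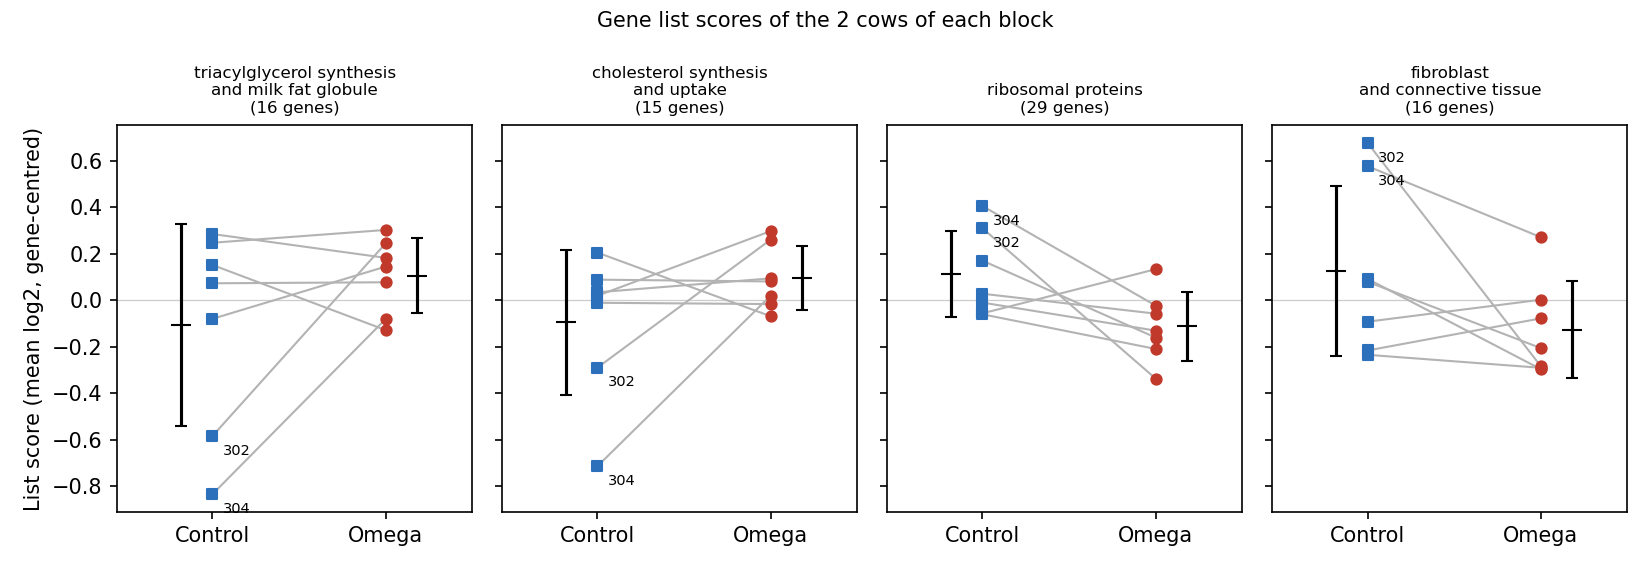
List scores (y axis, mean log2 of members centred per gene) of each cow in the 4 lists called for diet, with lines joining the cows of a block and bars giving the mean and SD (n = 7 per diet). The Control cows of blocks 302 and 304 are labelled, and in the triacylglycerol list they sit at -0.58 and -0.84 while the other 12 cows lie between -0.13 and 0.30.

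The lists for making and desaturating fatty acids were not called. In de novo fatty acid synthesis, 3 of 9 members were higher and the median was -0.12 log2 (camera adjusted p = 0.744). ACACA, the carboxylase that starts fatty acid synthesis, differed by 0.39 (-0.19 to 0.96), ACLY, which makes cytosolic acetyl-CoA, by -0.20, PGD by -0.26 and TKT by -0.12. In desaturation and elongation, 4 of 8 members were higher (adjusted p = 0.779). FADS2, the delta-6 desaturase, differed by 0.35 (0.03 to 0.66, limma adjusted p = 0.447), TECR by 0.25, ELOVL7 by -0.21 and ELOVL5 by -0.32. SCD, the delta-9 desaturase, was at 13.59 ± 0.15 in Omega and 13.44 ± 0.50 in Control cows (SD, n = 7 each), a fold of 1.11 with an interval of 0.869 to 1.41. Without blocks 302 and 304 the differences of SCD and ACACA were -0.12 and -0.048 log2.

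Fatty acid uptake, binding and activation had a median of 0.05 log2 over 11 members (adjusted p = 0.581). LPL differed by 0.24 (-0.45 to 0.93), ACSL1 by 0.25, FABP3 by 0.19, VLDLR by -0.27 and ACSL5 by -0.33. Without blocks 302 and 304, whose Control cows scored -0.20 and -0.66 in this list against -0.17 to 0.30, its median was -0.055, LPL differed by -0.20, FABP3 by -0.048 and ACSL5 by 0.15. Fatty acid oxidation had a median of 0.05 and a mean of -0.03 over 23 members (adjusted p = 0.613), with SLC25A20, the carnitine carrier, at -0.35 and HADHB at -0.58, and ACOX3 at -0.28 and ACOT8 at 0.30. The regulators SREBF1, INSIG1 and PPARG differed by 0.19 (-0.13 to 0.50), 0.17 (-0.30 to 0.64) and -0.19 (-0.64 to 0.26). SREBF1 and INSIG1 were at -0.030 and -0.027 without blocks 302 and 304. Milk proteins had a median of -0.01 over 11 members, opposite in sign to the camera direction (adjusted p = 0.779). LALBA, the lactose synthase cofactor, differed by -0.01 (-0.17 to 0.14), LTF by -0.82 (-2.41 to 0.77), B2M by -0.17, SPP1 by 0.18 and LPO by 0.30. Without blocks 302 and 304 the median was 0.020, and LTF differed by 0.10, B2M by 0.035 and LPO by -0.23.

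Of the inflammatory mediators and acute-phase genes, 3 of 19 were higher, with a median of -0.26 log2 (adjusted p = 0.581). The Control cows of blocks 302 and 304 scored 0.69 and 1.29 in this list, against at most 0.32 in the other 12, and without their blocks the median was 0.11. CCL3, a chemokine, differed by 0.46, TLR2, a pattern receptor, by -0.44, VCAM1 by -0.53 and NFKBIA by 0.44. Oxidative phosphorylation had 31 of 42 members higher and a median of 0.03 (adjusted p = 0.0671), with NDUFA8 at 0.18, UQCRB at 0.14 and NDUFB10 at -0.13. This list passed with quantile normalization (median 0.12), median centring, the stricter filter and calving day as a covariate, and without block 303, 304 or 305. Without block 306 its median was -0.00048. Immediate early and heat shock genes had a median of -0.08, opposite in sign to the camera direction (adjusted p = 0.935), with DUSP1 at 0.47, BAG3 at -0.49, HSP90AA1 at -0.43 and HSPB1 at -0.36. Its median was 0.013 without blocks 302 and 304.

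In all, camera called 4 of 34 lists for diet, and the medians of the 30 uncalled lists ran from -0.32 to 0.10 log2. The estimated correlation kept 0 of the 4 calls. The fry test called 0 lists in a common direction (smallest adjusted p = 0.738) and 0 in either direction (0.582). Adjusted over the list alone, 2 members passed, SLC5A1 among lactose and glucose transport genes and SOX18, an endothelial transcription factor, at -0.65 log2. This adjustment was made in each of the 34 lists separately and not across lists, so such passes can arise by chance. By the exact sign-flip test of the scores, the list of lactogenic and growth signalling was lower in 7 of 7 blocks (p = 0.0156, adjusted 0.531). The median and the camera direction differed in sign in 6 lists.

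Cows with a parity label of 1 (n = 4, blocks 302 and 306) were compared with the other 10. No gene passed. With limma, 0 of 7518 probe sets had an adjusted p under 0.05 (smallest 0.983), and 165 had an unadjusted p under 0.05, which was 85 without block 302, 102 without block 305 and 1103 without block 304 (smallest adjusted p = 0.179). By chance 375.9 of 7518 would be expected. The count was 80 of 4296 tested with the stricter filter and 250 of 10740 with no filter. It was 310 with previous milk as a covariate and 1742 with parity as a linear covariate. The median 95% confidence interval reached 0.29 log2 to either side. GATAD1 was 0.44 log2 higher in parity 1 (0.23 to 0.65), and MLF1 was 0.69, HNMT, which inactivates histamine, 0.57, CARHSP1 0.56, NMI 0.46 and PSMD5 0.44 higher. PHF6, IST1, BLOC1S6 and GLMP were 0.43, 0.34, 0.25 and 0.24 higher. LOXL2, a collagen cross-linking enzyme, differed by -0.76 (-1.32 to -0.21), COL13A1, a collagen, by -0.43, GJB2, a gap junction protein, by -0.43 and GPT, a transaminase, by -0.40. OOEP, CBLC, TMEM176B, SPEF1, OGFR and OSGIN1 differed by -0.38, -0.33, -0.32, -0.29, -0.26 and -0.23. With previous milk as a covariate NMI was at -0.0097 and SPEF1 at 0.079. Previous milk did not overlap between the classes, at 2110 to 2771 in parity 1 and 3635 to 4841 in the others. Parity and previous milk can therefore not be told apart in that fit.

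Camera called 2 of 34 lists for parity. Oxidative phosphorylation was higher in parity 1 in 38 of 42 members (median 0.07 log2, adjusted p = 0.0444), with ATP5F1A 0.18, NDUFB5 0.17, NDUFB3 0.17 and COX6B1 0.11 higher. Luminal epithelium markers had 9 of 9 members higher and a median of 0.16, and were not called (adjusted p = 0.107). Parity 1 includes the Control cow of block 302, whose luminal score was 0.81 against at most 0.35 in the 12 cows other than it and the Control cow of block 304. Immediate early and heat shock genes were lower, with 7 of 22 members higher (median -0.16, adjusted p = 0.0444). FOS, an early response transcription factor, differed by -1.42 (-2.91 to 0.07), ATF3 by -0.62, CCN1 by -0.57 and DUSP1 by -0.36. Both calls were lost with an estimated correlation (adjusted p = 0.906), and 0 members passed when adjusted over the list alone. Both were lost with median centring, with quantile normalization, with the array number as a covariate, with parity as a linear covariate and without block 304, 305 or 306. The first was also lost with the stricter filter and without block 302 or 308. Both calls were kept without block 303 or 307. They were kept too without the Control cows of blocks 302 and 304 (camera adjusted p = 0.00189 each). That setting was added after seeing the data. With previous milk as a covariate the median of the second turned to 0.51, with FOS at 1.08, ATF3 at 1.31, CCN1 at 0.37 and DUSP1 at 0.71. As previous milk did not overlap between the classes, these values do not tell parity from milk. Both cows of a block were in the same parity class, so the classes were compared between 2 blocks and 5.

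The diet difference was compared between the 2 blocks of parity 1 and the other 5. With limma, 0 of 7518 probe sets passed (smallest adjusted p = 1.00), and 125 had an unadjusted p under 0.05. By chance 375.9 of 7518 would be expected. Without block 304 or 305 the count was 202 or 72. Leaving out block 302 or 306 left 1 block of parity 1, a single pair of cows, so those counts are not given here. The count was 9 with array weights and 206 with previous milk as a covariate. It was 196 of 10740 tested with no filter and 59 of 4296 with the stricter filter. FBP2, a gluconeogenic bisphosphatase, had a diet difference of 1.47 log2 in parity 1 blocks and -1.20 in the others, RAB33B of -0.95 and -0.15, and CABP2 of 0.85 and -0.18. Oxidative phosphorylation was the single list called, with the diet difference higher in parity 1 in 37 of 42 members (median 0.15, camera adjusted p = 6.80e-06). With an estimated correlation its adjusted p was 0.989, and the call was lost without block 306, which left 1 block of parity 1. The Control cow of block 302, of parity 1, was among the arrays that stood apart. Without blocks 302 and 304, which left 1 block of parity 1, limma called 3 probe sets, C4BPA, an unnamed probe set with equal values and SLC16A1, named after their values were seen.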

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

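The tests of the 2 Control cows, of the calls without them and of the interaction lists over block choices were chosen after the results were seen.

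In 7 of 134 groups of values tested, 1 cow lay far from the rest, where about 6.7 groups would by chance. ITGB5 was at 6.53 log2 in the Omega cow of block 304, with the next Omega cow at 5.93. ACACA was at 5.93 in the Omega cow of block 306, with the next at 6.24. TMEM50B was at 7.04 in the Control cow of block 306, with the next at 7.27. The mean 3' minus 5' difference of the control probe sets was 0.790 log2 in the Control cow of block 307, with the next at 0.632. Among parity 1 cows, IST1 was at 9.11 in the Control cow of block 302, with the next at 8.60. Among the 10 cows of higher parity, PSMD5 was at 8.60 in the Omega cow of block 304, with the next at 8.15, and GLMP was at 6.07 in the Omega cow of block 308, with the next at 5.96. The diet difference of oxidative phosphorylation differed between parity classes by a median of 0.15 log2.

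The Control cows of blocks 302 and 304 differed from the other 12 in 1180 of 4932 genes above and 712 below the range, where chance gives 54.2 each way for a pair named beforehand. RNA degradation is argued against, since their 3' minus 5' differences (at most 0.525) lay below the range reaching 0.790, as is weak hybridization, with spike-ins at 10.6 inside the range reaching 11.3. On the first principal component, 0 of the other 5 Control cows lay above the highest Omega cow. The Control cows of blocks 302 and 304 were set apart by the same scores, so this count restates the pattern. It shows that the control diet did not set every Control cow apart, and is no separate test of that diet as a cause. Luminal scores of at least 0.722 lay above the highest of 0.353, the opposite of a lower share of epithelium. Fibroblast scores of 0.68 and 0.58 also lay above the range, which reached 0.27, while endothelium scores lay inside it. Such scores do not tell cell shares from regulation of the listed genes, so a changed share of epithelium stays open. A gland with an acute-phase response and less milk fat synthesis is a candidate explanation that was not tested: it was formed from these cows' values, so their inflammatory scores of at least 0.687, against a highest of 0.317, restate it. Udder health is not given in the sources used here, and the poly-A spike-ins lay below the range (6.60 and 6.34 against 6.92 to 7.63), so RNA input or labelling stays open.

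Of the 4 lists called for diet, 3 may rest on blocks 302 and 304, since their calls were lost without these blocks. The Omega cows of these blocks were left out too, so the loss does not single out the 2 Control cows. Without block 302 alone the triacylglycerol, cholesterol and fibroblast calls were already lost (camera adjusted p = 0.314, 0.0552 and 0.168). Of the 20 other pairs of blocks, 1 (302 and 308) also cost 3 calls. Chance could not be excluded for the number of lists, as 34 of the 64 splits that part all 7 pairs called at least 4, and the highest of the others called 15. An effect of linseed on part of the lists stays open.

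The 827 probe sets at an unadjusted diet p under 0.05 were reached by 5 of the 64 splits, with 1403 in the highest other, so chance could not be excluded. Splits that kept the Control cows of blocks 302 and 304 on the same side had a median of 556 probe sets, and splits that parted them 137.5. For parity, 73 of 100 splits, the real one included, reached 165 probe sets (highest other 2324) and 83 reached 2 lists (highest other 17). These splits ignored the blocks; of the 21 choices of 2 whole blocks, 13 reached as many probe sets (highest 1932) and 19 as many lists (highest 15). Chance could not be excluded, and counts several times the real one point to a structure of the samples. For the interaction, 18 of the 21 choices of 2 blocks reached 125 probe sets (highest other 2255) and 19 reached 1 list (highest other 15). The choice of blocks 302 and 304 called 808 probe sets, which points to the structure set by these cows.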

How the results depend on the processing

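The settings without blocks 302 and 304, without their Control cows, with the hybridization covariate and with equal rows counted a single time were chosen after seeing the data, and so were all list counts for the interaction. The calls of single genes stayed at 0 for diet and parity in every setting run, and leaving the block out of the diet fit gave 791 probe sets at an unadjusted p under 0.05 and 4 lists. The smallest adjusted p for diet ran from 0.194 to 0.779 over the alternatives. Over 146 alternatives of counts, 110 stayed within 1.5 times the main count or were 0 like it. Many of the 110 were counts of called single genes, at 0 in both fits, which says little about stability. Of 2139 alternatives of named genes 2116 kept direction and 23 turned. None of these genes passed the threshold in the main fit or in an alternative. Of 323 alternatives for lists 256 kept direction and side of the threshold, with 40 losing a call, 7 gaining one and 20 turning. Robust eBayes was not run for lists, a second pseudocount was not needed for log values, and signal over background was not tested. The cause of a change was not tested except where fewer cows or genes entered the fit.

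Without blocks 302 and 304, 494 probe sets had an unadjusted diet p under 0.05 and 1 diet list was called. The interaction then called 3 probe sets, C4BPA at 5.54 log2 with an unnamed probe set of equal values and SLC16A1 at -2.00, and 7 lists. These rest on the single parity 1 block left, assumed to vary like the others. Medians turned for cholesterol (-0.013), triacylglycerol (-0.012), fatty acid uptake (-0.055), heat shock (0.013), inflammatory (0.11) and milk protein lists (0.020). Genes that turned were ACACA (-0.048), ACSL5 (0.15), B2M (0.035), FABP3 (-0.048), INSIG1 (-0.027), LPL (-0.20), LPO (-0.23), LTF (0.10), SCD (-0.12) and SREBF1 (-0.030). Without the Control cows of blocks 302 and 304, 5 parity lists were called.

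With each block left out in turn, the diet probe sets at an unadjusted p under 0.05 ran from 434 (block 304) to 1229 (block 306) and reached 516 without block 303. Diet lists ran from 1 (block 302) to 7 (block 306), parity lists from 0 (block 305) to 6 (block 304), and interaction lists from 1 to 8 (block 304). The interaction fits without block 302 or 306 left 1 block of parity 1 and are not read here. Ranges that crossed 0 were LPL (-0.094 to 0.45), LPO (-0.0014 to 0.50), LALBA (-0.025 to 0.0014) and INSIG1 (-0.035 to 0.30). List medians did so for fatty acid uptake (-0.094 to 0.078), oxidation (-0.020 to 0.056), desaturation (-0.081 to 0.010), milk proteins (-0.017 to 0.011) and oxidative phosphorylation (-0.00048 to 0.071).

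Camera with an estimated correlation and fry each called 0 diet, 0 parity and 0 interaction lists. Array weights called 1 diet list, ribosomal proteins, so the cholesterol, triacylglycerol and fibroblast calls were lost. All cows were kept, but deviating arrays can get less weight, and the weights are not given here. The same setting called 7 parity and 2 interaction lists, with SCD at -0.025, LPO at -0.052 and the oxidation median at -0.00050. Quantile normalization called 0 parity and 2 interaction lists, with milk proteins at 0.0018, and median centring 0 and 2, with LALBA at 0.033, milk proteins at 0.039 and desaturation at 0.012. With the 60th percentile as filter, 482 of 4296 tested probe sets had an unadjusted diet p under 0.05, and 4 parity lists were called. Without a filter, desaturation was at 0.020 and fatty acid uptake at -0.013. The array number left 0 parity lists, calving day gave 2 interaction lists, and parity as a linear covariate called 8 parity lists. Previous milk gave 2 interaction lists and turned the parity values of FOS (1.08), ATF3 (1.31), DUSP1 (0.71), CCN1 (0.37), SPEF1 (0.079), NMI (-0.0097) and the heat shock list (0.51). Previous milk did not overlap between the parity classes, so these turned values do not tell parity from milk.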

Other observations

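The test of the acute-phase and milk fat lists was chosen after the 2 Control cows were seen, and the genes named in this part were chosen after their values were seen. In the Control cows of blocks 302 and 304, many immune transcripts lay above the range of the other 12, while CD14 (6.41 and 6.27 log2 against 6.27 to 7.48) and TLR2 (8.15 and 8.23 against 7.48 to 9.25), receptors for bacterial products, lay inside it. CHI3L1, a secreted lectin, stood at 12.49 and 12.52 log2 against 4.35 to 8.90, and CFI, a complement regulator, at 9.29 and 9.50 against 3.70 to 6.93. LTF, the iron-binding milk protein lactoferrin, stood at 14.20 and 14.37 against 8.69 to 12.90, LBP, which binds bacterial lipopolysaccharide, at 10.29 and 9.95 against 6.48 to 8.46, and SOD2, a mitochondrial antioxidant enzyme, at 13.22 and 13.30 against 9.79 to 11.27. The list of complement genes scored 1.31 and 1.68 against at most 0.66, with 8 of 12 members above the range in both cows. Neutrophil markers scored 1.10 and 1.47 against at most 0.56, with 3 of 7 members above, and macrophage and dendritic markers 0.84 and 0.89 against at most 0.20, with 11 of 13 above. Several of these genes are also made by mammary epithelium.

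Several synthesis and transport genes lay below the range in the same cows, with 1 exception among those named. SLC7A5, an amino acid transporter, stood at 7.40 and 7.76 log2 against 7.71 to 10.64, so that 1 of the 2 was inside. GPAT4, which starts glycerolipid synthesis, stood at 7.31 and 6.86 against 7.79 to 9.42, ABCG2, a milk transporter, at 10.99 and 10.32 against 11.86 to 12.99, and BTN1A1, a globule membrane protein, at 12.75 and 12.44 against 13.26 to 13.60. Among the caseins, CSN1S1 stood at 13.73 and 13.46 against 13.57 to 13.91, so that the Control cow of block 304 lay below the range. CSN3 stood at 14.744 and 14.730, above the range of 14.634 to 14.728, and CSN1S2 at 14.57 and 14.60, inside 14.51 to 14.63, both near the top of the scale, where differences are compressed. The milk protein list scored 0.19 and 0.21 in these cows, above the highest of 0.11. It includes LTF, whose high values raise the score, and 3 of its 11 members lay above the range in both cows and 1 below. The score therefore does not show that milk protein transcripts rose as a group. The endothelium scores of 0.08 and -0.14 lay inside the range of the other 12. The Omega cow of block 306 had the highest SAA3 (10.20) and the lowest LPL (11.49) of the other 12.

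The hypothesis that acute-phase and milk fat transcripts move oppositely may extend to the other 12 cows, but the test leaves it open. Across them the inflammatory and triacylglycerol scores correlated at Pearson r = -0.62 (permutation p = 0.0244) and Spearman rho = -0.64 (permutation p = 0.0299), in 1 relation computed. Without the 2 cows farthest from the median of the inflammatory score, the Omega cows of blocks 306 and 302, r was -0.32 (permutation p = 0.373). The relation thus did not pass without them. Leaving out the farthest values also narrows the spread of the score, so this does not show that the relation rests on those cows. Within the 7 Omega cows r was -0.73 (exact permutation p = 0.0431), but these include the same 2 cows, and no correlation was computed over the 5 Omega cows without them or the 5 remaining Control cows.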
